A study of Homo sapiens with 12 samples.

How the data were processed

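RNA was measured in 12 libraries of T84 cells, an established human colon carcinoma line that grows as a polarised epithelial sheet. Per the labels' protocols, confluent cells in multiwell plates had their medium exchanged for Hanks buffered saline of pH 7.4 or pH 6.0, were held there for 3 h or 6 h and were lysed in Trizol, and the total RNA was made into libraries by Illumina's usual procedure. The labels give 4 groups of 3 libraries, with no batch, date or culture of origin. Because nothing in the labels says that the libraries of a group came from separate cultures, every p-value measures only the spread between these libraries, which may be technical.

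Each deposited table holds, for 48162 Ensembl gene identifiers, a read count made by the authors and an RPKM value made by the authors from it. Per the submitters' processing notes the tools were STAR and CASAVA and the genome build was hg19. Tool versions, the gene annotation, the counting program and its use of strand are not given in the sources used here. Gene lengths were recovered from the tables, as the median over libraries of the length implied by a gene's count, library total and RPKM. With these lengths 100.0% of the RPKM values were reproduced within a relative tolerance of 1e-06. That shows only that a single length per gene served all libraries and is no independent check. The recovered lengths were used wherever gene length appears below, and the RPKM values for nothing else. All tests used the deposited counts. Of the identifiers, 30685 had a count in at least 1 library. Gene symbols came from the names tables and from a GENCODE 29 annotation of GRCh38, which is not the authors' build and was used only for names, biotypes, GC content and exon overlap. A symbol was found for 45342 identifiers, clone-style names such as AL359955.1 included, and genes without a symbol took between 0.881% and 1.11% of the counts of a library. No coordinates are given, since the tables hold none.

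Libraries held between 13912532 and 24331032 counts. The counts of any pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom from 5.40 to 19.5 over the 12 pairs, over genes with at least 20 counts in the pair), so no library was a second copy of another. The biological coefficient of variation common to all genes was 9.29%.

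Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by robust quasi-likelihood F tests with TMM factors and edgeR's default expression filter, which left 15630 genes. A single fit held all 12 libraries in 4 groups, with 8 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. The standard error of a log2 fold change was its size divided by the square root of its F statistic. Contrasts compared pH 6.0 with pH 7.4 at each time and averaged over times, 6 h with 3 h at each pH, and the pH effect at 6 h with that at 3 h (the interaction). CPM values use TMM-scaled totals.

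In all, 45 gene lists were fixed beforehand, and the 44 with at least 5 tested genes entered camera (limma 3.58.1) with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Of the list entries, 1190 matched a symbol directly, 21 matched a RefSeq synonym, 36 a GENCODE 29 name, and 37 matched nothing. Endothelial markers had 4 tested genes and entered no test. The averaged pH effect had no list test. Every list test was repeated with the correlation estimated from the residuals of each list.

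The groups, contrasts, lists, alternatives and the rule for naming genes were set before the data were examined. For pH at each time the rule takes the 10 higher and 10 lower genes with the largest absolute log2 fold change among changed genes with a mean count of at least 100 and fully separated libraries, up to 4 members per described list with the smallest p, and a fixed set of acid-handling genes whatever their result. For the interaction and for time it takes the 5 higher and 5 lower genes, the interaction without the condition on separated libraries, and list members likewise. The text leaves out part of the list members. Part of the fixed set of acid-handling genes is not reported here.

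Alternatives were DESeq2 1.42.0 on all genes with a count (with 0.05 as the level of its independent filtering), median-of-ratios factors, total counts alone, no filter, a filter of 5 CPM in at least 3 libraries, a fit of only the groups compared, the replicate number as a term, edgeR's test against a fold change of 1.2, and each library left out in turn. A correction for gene length and GC content, by natural splines with 5 degrees of freedom per library, and a scan of gene families by symbol were chosen after seeing the data.

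The procedure was tested on simulated counts with known changes. The changed genes were not drawn from the most weakly expressed ones. Counts were drawn independently for each gene and, apart from the length trend below, without a trend between libraries. The recovered shares therefore do not cover weakly expressed genes or genes that vary together. For pH at 3 h (15270 simulated genes tested) it recovered 67% of genes changed 1.5-fold and 90% of genes changed 2-fold, for pH at 6 h 68% and 96%, and for the interaction 42.5% and 85%. For the averaged effect, with each gene changed at 1 time only, it recovered 38% and 82.5%. With the simulated change placed at pH 6.0, the test of time at pH 6.0 recovered 69% and 94%. A simulated trend with gene length at 6 h made 2681 unchanged genes of 15216 tested pass, and 15 after the length and GC correction, so a call in the main tests can reflect such a trend.

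A gene whose exons overlap another annotated gene, on either strand, can share reads with it when strand use is not stated, and so can near-identical copies. Such genes are named as uncertain where they appear.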

Results

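The series measured mRNA in T84 cells, a human colon carcinoma line used as a model of the intestinal epithelium, under saline of pH 7.4 or pH 6.0 for 3 h or 6 h. Its stated subject is the response of intestinal epithelial cells to acidosis. Each of the 4 groups had 3 libraries. At 3 h they held 16865263 to 24331032 counts at pH 7.4 and 13912532 to 18205946 at pH 6.0. At 6 h they held 16574741 to 18921141 counts at pH 7.4 and 15383041 to 20525403 at pH 6.0. Mitochondrially encoded genes took 8.93% ± 1.49, 8.47% ± 0.917, 8.51% ± 0.504 and 7.28% ± 0.131 of the counts in these groups in that order (SD, n = 3 each). Markers of other cell types were low. The most abundant of the 17 fibroblast markers was TAGLN, at up to 7.50 CPM in any group mean. Among the 21 leukocyte markers it was LYZ, at up to 8.85 CPM, and among the 11 endothelial markers ESAM, at up to 13.2 CPM. Neither the fibroblast nor the leukocyte list changed as a whole with pH at either time, with time at either pH or in the interaction. Below, a value after ± is a standard error (SE) of a log2 fold change from edgeR with n = 3 libraries per group, unless marked as an SD.

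At 3 h, the largest increases at pH 6.0 included NR4A1, FOS and FOSB, and the largest decreases included MYC, the amino acid transporter gene SLC38A2, ID1 and SMAD7. The orphan nuclear receptor NR4A1 (ENSG00000123358) went from 43.9 ± 2.35 CPM at pH 7.4 to 310.2 ± 24.2 CPM at pH 6.0 (SD, n = 3), a log2 fold change of 2.82 ± 0.10 (adjusted p = 2.25e-15). The AP-1 subunits FOS (2.58 ± 0.09) and FOSB (2.61 ± 0.18), the stress sensor GADD45B (2.40 ± 0.12), the zinc finger factor EGR2 (2.12 ± 0.18) and the MAP kinase phosphatases DUSP1 (2.12 ± 0.11) and DUSP2 (2.05 ± 0.14) also rose, with adjusted p between 2.25e-15 and 2.86e-08. The proto-oncogene MYC (ENSG00000136997) fell from 193.4 ± 7.43 to 60.3 ± 10.7 CPM (SD), a log2 change of -1.68 ± 0.10 (adjusted p = 4.36e-11). The neutral amino acid transporter SLC38A2 fell from 654.7 ± 36.3 to 197.2 ± 8.12 CPM (SD; log2 -1.73 ± 0.08). RASSF10 (-1.93 ± 0.12), the BMP target ID1 (-1.71 ± 0.18), the inhibitory SMAD gene SMAD7 (-1.65 ± 0.13), the forkhead factor FOXQ1 (-1.63 ± 0.11) and the kinase gene SGK1 (-1.56 ± 0.14) fell as well. The non-coding transcripts AL359955.1, a pseudogene (2.15 ± 0.21), KCNQ1OT1 (2.07 ± 0.28) and MIR23AHG (2.05 ± 0.15) rose too. The libraries of the pH groups did not overlap in CPM for any of these genes, which the rule for naming them required. In all, 2937 of 15630 genes changed, 1489 higher and 1448 lower. Among them 356 of the higher but 92 of the lower genes moved at least 2-fold.

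Of 44 gene lists, 21 changed as a whole at 3 h, 13 higher and 8 lower, and 1 of them, the cAMP/CREB targets, also passed with an estimated correlation. With the preset correlation, other splits of the same libraries called a median of 8 lists at 3 h and 13 at 6 h. Each of these splits mixes the pH values unevenly and keeps part of the pH difference, so it does not show what chance alone gives. The number of lists is therefore not taken here as evidence of an effect of pH. Of the 18 tested cAMP/CREB targets 9 rose and 3 fell (10 and 3 adjusted over the list alone), with a median log2 change of 0.57 (adjusted p = 9.03e-29 over the lists, adjusted p = 0.00141 with an estimated correlation). The member PCK1, the rate-limiting enzyme of gluconeogenesis, rose by 1.95 ± 0.12. Of 37 immediate early genes 18 rose and 5 fell (21 and 7 adjusted over the list alone), at an adjusted p = 1.19e-19 for the list and an adjusted p = 0.0808 with an estimated correlation. EGR1 rose by 1.89 ± 0.09. The integrated stress response (ATF4) targets went the other way: 22 of 35 fell and 1 rose (28 and 3 adjusted over the list alone), at an adjusted p = 2.04e-18 for the list and an adjusted p = 0.0808 with an estimated correlation. Its median was -0.46. CHAC1, a glutathione-degrading enzyme, fell (-1.44 ± 0.15), as did the transcription factor CEBPB (-0.86 ± 0.09), whereas ATF3, also an immediate early gene, was the member that rose (1.01 ± 0.09).

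Among HIF targets 16 of 30 rose and 1 fell, and among glycolysis genes 10 of 26 rose and none fell (19 and 2, and 13 and 0, adjusted over each list alone). The glucose transporter SLC2A1 (0.75 ± 0.08), hexokinase HK2 (0.82 ± 0.09) and the fructose bisphosphate regulator PFKFB3 (0.69 ± 0.08) were among them. The list adjusted p was 1.71e-08 for HIF targets and 3.29e-07 for glycolysis, with adjusted p = 0.127 with an estimated correlation for each. Cholesterol synthesis genes rose in 10 of 25 cases (12 adjusted over the list alone, with 1 lower), at an adjusted p = 1.08e-05 for the list and an adjusted p = 0.281 with an estimated correlation. INSIG1, a sterol-sensing regulator, rose by 0.99 ± 0.09 and the synthase HMGCS1 by 0.70 ± 0.08. Heat shock genes rose in 7 of 26 cases and fell in 1 (7 and 1 adjusted over the list alone), at an adjusted p = 0.00173 for the list and an adjusted p = 0.267 with an estimated correlation. HSPA1B rose by 1.45 ± 0.10 and its co-chaperone DNAJB1 by 0.74 ± 0.09. Of 18 TGF-beta targets 8 fell and 1 rose (8 and 1 adjusted over the list alone), at an adjusted p = 3.01e-06 for the list and an adjusted p = 0.0963 with an estimated correlation. ID3 fell (-1.25 ± 0.12.) Of 31 type I interferon-stimulated genes 11 fell and 3 rose (14 and 3 adjusted over the list alone), at an adjusted p = 0.00515 for the list and an adjusted p = 0.281 with an estimated correlation. IFIT2 (-0.61 ± 0.09) and IFIT1 (-0.37 ± 0.07) were among those that fell.

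The NF-kB list was mixed at 3 h, with 7 of 32 members higher and 4 lower (8 and 6 adjusted over the list alone). Its feedback inhibitors TNFAIP3 (1.35 ± 0.09) and NFKBIA (0.84 ± 0.10) rose (list adjusted p = 0.00351, adjusted p = 0.374 with an estimated correlation). Of 21 Wnt targets and stem cell genes 5 fell and 1 rose (5 and 2 adjusted over the list alone). The pathway inhibitors AXIN2 (-1.11 ± 0.10) and DKK1 (-1.39 ± 0.15) fell and the receptor-degrading ligase RNF43 rose (0.60 ± 0.08). This list tested as lower (adjusted p = 0.0224, adjusted p = 0.127 with an estimated correlation). Its median of -0.03 became 0.01 after the length and GC correction, although the list still passed after it with the preset correlation. The clock gene PER1 rose by 1.29 ± 0.09. Ribosomal proteins tested as lower as a list (median -0.21, adjusted p = 3.58e-04, adjusted p = 0.776 with an estimated correlation), although 1 of 73 members passed, and none adjusted over the list alone. That member, RPL6 (-0.35 ± 0.10, adjusted p = 0.0221), missed the threshold without the first library at pH 7.4 (adjusted p = 0.0986) and without the second (0.126) or the third (0.0714) library at pH 6.0. The list is of short genes (median 1747 bases). Over all genes the median log2 change at 3 h was 0.13, -0.12 and 0.17 in the shortest, second and longest decile by length. Deviations from gene means correlated with length at -0.23, -0.09 and -0.14 in the pH 7.4 libraries and -0.22, 0.16 and -0.01 at pH 6.0 (Spearman).

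The count of 2937 genes fell to 1661 without the first library at pH 7.4 and to 1649 and 1648 without the second and the third library at pH 6.0. With total counts in place of TMM factors the split was 1194 higher and 1752 lower. NR4A1, KCNQ1OT1, MIR23AHG, SLC2A1, DNAJB1, TNFAIP3, IFIT2, HMGCS1, AXIN2, DKK1, RNF43, PER1 and RPL6 overlap exons of other annotated genes, and HSPA1B and AL359955.1 have near copies, so their counts are uncertain to that extent.

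**Figure D1:**
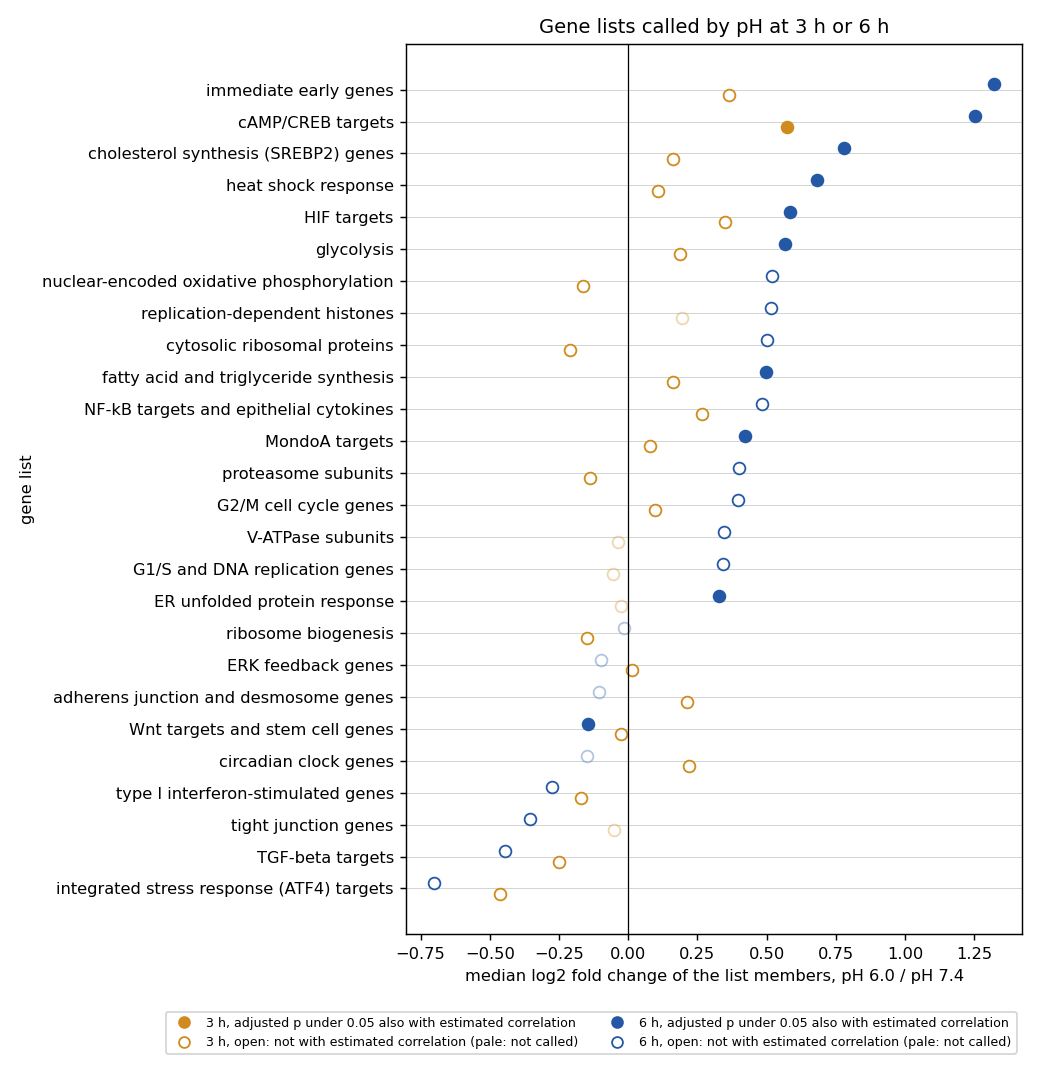
Median log2 fold change (pH 6.0 against pH 7.4, x axis) over the tested members of each gene list that changed as a whole at 3 h (orange) or 6 h (blue). Filled points also passed with an estimated correlation, open points did not, and pale points were not called; immediate early genes have the highest median at 6 h (1.32) and ATF4 targets the lowest (-0.70).

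At 6 h, immediate early, cholesterol synthesis, heat shock and glycolysis genes were each higher as a list at pH 6.0 (adjusted p = 0.0163, 0.0135, 0.0124 and 0.0408 with an estimated correlation). GADD45B (ENSG00000099860) went from 5.32 ± 0.397 to 125.2 ± 8.43 CPM (SD, n = 3), a log2 fold change of 4.55 ± 0.12 (adjusted p = 1.3e-17). NR4A1 went from 55.1 ± 6.40 to 1041 ± 69.7 CPM (SD; 4.24 ± 0.10, adjusted p = 1.53e-18). FOSB (4.48 ± 0.17), the synaptic regulator ARC (3.99 ± 0.26), RND1 (3.88 ± 0.23), DUSP2 (3.43 ± 0.14), EGR2 (3.21 ± 0.18), PCK1 (3.17 ± 0.12), TENT5B (3.14 ± 0.21) and EGR3 (3.10 ± 0.17) completed the 10 largest increases. MYC fell from 200.6 ± 3.58 to 24.5 ± 1.66 CPM (SD; -3.03 ± 0.10, adjusted p = 9.71e-16). SLC38A2 fell from 1330.1 ± 18.2 to 248.2 ± 21.4 CPM (SD; -2.42 ± 0.08). The largest other decreases were those of the non-coding AC012531.1 (-3.51 ± 0.38), RASSF10 (-3.04 ± 0.14), the Wnt pathway gene FRAT1 (-2.81 ± 0.23), FOXQ1 (-2.70 ± 0.12), HPS6 (-2.70 ± 0.12), AXIN2 (-2.66 ± 0.11), the glycine transporter SLC6A9 (-2.49 ± 0.12) and NCOA5 (-2.47 ± 0.11). The pH groups did not overlap for any of these genes, again by the rule for naming them. In all, 7342 genes changed, 3418 higher and 3924 lower, 640 and 830 of them at least 2-fold. The majority turned with the length and GC correction (3890 higher and 3516 lower), with the stricter filter (3317 and 3119) and without any 1 of the pH 6.0 libraries.

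Of the 44 lists, 22 changed at 6 h, 17 higher and 5 lower, and 10 also passed with an estimated correlation. Of 37 immediate early genes 27 rose and 7 fell, also 27 and 7 adjusted over the list alone, at an adjusted p = 8.52e-31 for the list and an adjusted p = 0.0163 with an estimated correlation. The median was 1.32. Cholesterol synthesis genes rose in 23 of 25 cases, also 23 adjusted over the list alone, at an adjusted p = 5.76e-30 for the list and an adjusted p = 0.0135 with an estimated correlation. The median was 0.78. INSIG1 went from 72.8 ± 5.02 to 463.2 ± 36.2 CPM (SD; log2 2.67 ± 0.09), with HMGCS1 at 2.43 ± 0.08 and the demethylating enzyme MSMO1 at 2.36 ± 0.09. Fatty acid and triglyceride synthesis genes rose in 13 of 19 cases and fell in 1, also 13 and 1 adjusted over the list alone (adjusted p = 1.44e-04, adjusted p = 0.0474 with an estimated correlation). The acetyl-CoA-forming enzymes ACSS2 (0.90 ± 0.09) and ACLY (0.64 ± 0.07) were among those that rose. With time at pH 7.4 this list fell (adjusted p = 4.66e-04, adjusted p = 0.0857 with an estimated correlation). With time at pH 6.0 it did not pass (median 0.054, adjusted p = 0.899). Heat shock genes rose in 20 of 26 cases and fell in 2, also 20 and 2 adjusted over the list alone (median 0.68, adjusted p = 1.11e-16, adjusted p = 0.0124 with an estimated correlation). HSPA1B rose by 2.66 ± 0.11 and DNAJB1 by 2.31 ± 0.09. Of 28 genes of the ER unfolded protein response 15 rose and 3 fell (16 and 3 adjusted over the list alone), at an adjusted p = 0.00485 for the list and an adjusted p = 0.0474 with an estimated correlation. The chaperone HSPA5 (1.02 ± 0.08) and HERPUD1 (1.12 ± 0.07) rose and the sensor kinase gene ERN1 fell (-1.41 ± 0.13).

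Glycolysis genes rose in 22 of 26 cases and HIF targets in 23 of 30, with 1 lower in each (23 and 1 in each adjusted over the list alone). PGAM1, a mutase of glycolysis, rose by 1.38 ± 0.08, lactate dehydrogenase LDHA by 1.03 ± 0.09 and NDRG1 by 1.95 ± 0.11. The HIF target STC2 fell (-0.91 ± 0.08). The list adjusted p was 4.53e-13 for glycolysis (adjusted p = 0.0408 with an estimated correlation) and 5.67e-11 for HIF targets (adjusted p = 0.0474 with an estimated correlation). At pH 7.4, 15 of 26 glycolysis genes and 11 of 30 HIF targets fell with time, and 3 in each rose. Both lists passed as lower with the preset correlation (adjusted p = 5.78e-05 and 0.0107) but not with an estimated one (0.199 and 0.4). At pH 6.0 neither list passed with time (medians 0.128 and 0.117, adjusted p = 0.052 for each). The difference in these lists at 6 h thus holds a fall at pH 7.4. MondoA targets rose in 7 of 10 cases and fell in 1, also 7 and 1 adjusted over the list alone, at an adjusted p = 0.00274 for the list and an adjusted p = 0.0474 with an estimated correlation. KLF10 rose by 1.16 ± 0.09. The cAMP/CREB targets split into 10 higher and 4 lower of 18 (10 and 6 adjusted over the list alone) and were higher as a whole, at an adjusted p = 9.51e-23 for the list and an adjusted p = 0.00342 with an estimated correlation. PER1 rose by 2.31 ± 0.09 and DUSP1 by 2.92 ± 0.10. NF-kB targets rose in 13 of 32 cases and fell in 4 (14 and 4 adjusted over the list alone), at an adjusted p = 1.49e-06 for the list and an adjusted p = 0.104 with an estimated correlation. TNFAIP3 rose by 2.33 ± 0.10 and NFKBIA by 1.97 ± 0.10.

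Wnt targets and stem cell genes fell in 10 of 21 cases and rose in 5, also 10 and 5 adjusted over the list alone (adjusted p = 5.55e-05, adjusted p = 0.0161 with an estimated correlation). The list median of -0.14 became 0.02 after the length and GC correction, although the list still passed after it with the preset correlation. SOX9, a progenitor transcription factor, fell by 1.64 ± 0.08 on the log2 scale. ATF4 targets fell in 24 of 35 cases and rose in 4 (25 and 4 adjusted over the list alone), at an adjusted p = 1.5e-10 for the list and an adjusted p = 0.088 with an estimated correlation. The serine synthesis enzyme PSAT1 fell (-1.41 ± 0.08), and ATF3 again rose (1.96 ± 0.09). TGF-beta targets fell in 10 of 18 cases and rose in 1, also 10 and 1 adjusted over the list alone, at an adjusted p = 2.16e-04 for the list and an adjusted p = 0.088 with an estimated correlation. SMAD7 fell by 1.85 ± 0.14 and ID3 by 1.28 ± 0.12 on the log2 scale. Interferon-stimulated genes fell in 17 of 31 cases and rose in 4 (17 and 5 adjusted over the list alone), at an adjusted p = 1.7e-04 for the list and an adjusted p = 0.105 with an estimated correlation. IFIT3 (-1.29 ± 0.08) was among those that fell, and the RNA sensor RIGI was 2.29-fold lower. Of 24 tight junction genes 18 fell and 3 rose (18 and 4 adjusted over the list alone), at an adjusted p = 0.00274 for the list and an adjusted p = 0.0968 with an estimated correlation. CLDN1 (-1.58 ± 0.08) and the scaffold TJP1 (-1.01 ± 0.09) fell and CLDN4 rose (1.30 ± 0.09). With time at pH 7.4 tight junction genes rose, with 12 of 24 higher and 0 lower (adjusted p = 4.13e-07). With time at pH 6.0 they did not pass, with 5 higher and 3 lower (median -0.007, adjusted p = 0.241). The difference in this list at 6 h thus holds a rise at pH 7.4.

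Further lists were higher at 6 h with the preset but not with an estimated correlation. Ribosomal proteins rose in 60 of 73 cases (66 adjusted over the list alone), at an adjusted p = 5.52e-11 for the list and an adjusted p = 0.438 with an estimated correlation. Their median was 0.50, and RPS3A rose by 0.67 ± 0.10. Nuclear-encoded oxidative phosphorylation genes rose in 38 of 54 cases (41 adjusted over the list alone), at an adjusted p = 1.79e-07 for the list and an adjusted p = 0.438 with an estimated correlation. UQCRC2 rose by 0.46 ± 0.07. Proteasome subunits rose in 22 of 30 (23 adjusted over the list alone, with 1 lower), at an adjusted p = 1.17e-04 for the list and an adjusted p = 0.484 with an estimated correlation. PSMD4 rose by 0.60 ± 0.09. G2/M genes rose in 22 of 33 cases and fell in 1 (22 and 2 adjusted over the list alone), at an adjusted p = 3.06e-06 for the list and an adjusted p = 0.209 with an estimated correlation. CCNA2 rose by 0.84 ± 0.08 and CKS2 by 1.25 ± 0.13. G1/S genes rose in 24 of 40 cases and fell in 4 (25 and 4 adjusted over the list alone), at an adjusted p = 0.00151 for the list and an adjusted p = 0.56 with an estimated correlation. The helicase subunit MCM2 rose by 0.60 ± 0.08. From 3 h to 6 h at pH 7.4 both cell cycle lists fell. There 17 of 33 G2/M genes fell and 1 rose (adjusted p = 4.08e-05, adjusted p = 0.317 with an estimated correlation). Of 40 G1/S genes 25 fell and 0 rose (adjusted p = 2.77e-08, adjusted p = 0.347 with an estimated correlation). With time at pH 6.0 neither list passed (medians 0.125 and 0.034, adjusted p = 0.633 and 0.864). Subunits of the proton-pumping V-ATPase rose in 13 of 18 cases and fell in 1, also 13 and 1 adjusted over the list alone, at an adjusted p = 0.0231 for the list and an adjusted p = 0.389 with an estimated correlation. ATP6AP2 rose (0.62 ± 0.08) and ATP6V0A2 fell (-0.62 ± 0.09). Beside these stands a trend with transcript length at 6 h. The median log2 change was 0.27 in the second decile of genes by length and -0.32 in the longest decile, with a Spearman correlation of -0.27 across 15630 genes, which are not independent replicates.

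NR4A1, EGR3, AXIN2, SLC6A9, HMGCS1, DNAJB1, PER1, TNFAIP3, MCM2, RPS3A and CCNA2 overlap other annotated exons, and HSPA1B and the ribosomal protein genes have near copies, so these values are uncertain. No other scaling, filter or left-out library moved the count at 6 h by over 1.5 times, but the test against a fold change of 1.2 left 4464 genes (700 at 3 h).

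**Figure D2:**
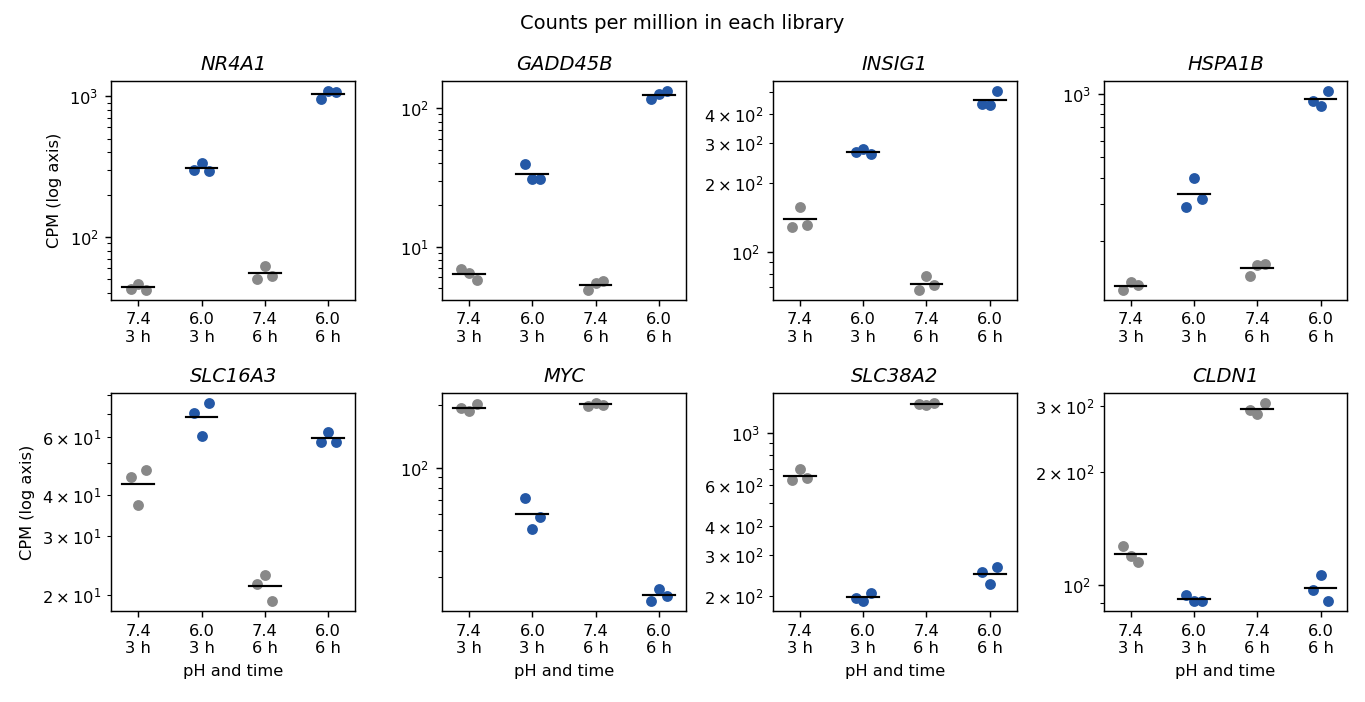
CPM (log axis) in each of the 12 libraries for 8 genes, with pH 7.4 in grey and pH 6.0 in blue at 3 h and 6 h; the line is the mean of 3 libraries. NR4A1 reached a mean of 1041 CPM at pH 6.0 and 6 h against 55.1 CPM at pH 7.4, and MYC fell to 24.5 CPM.

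**Figure D3:**
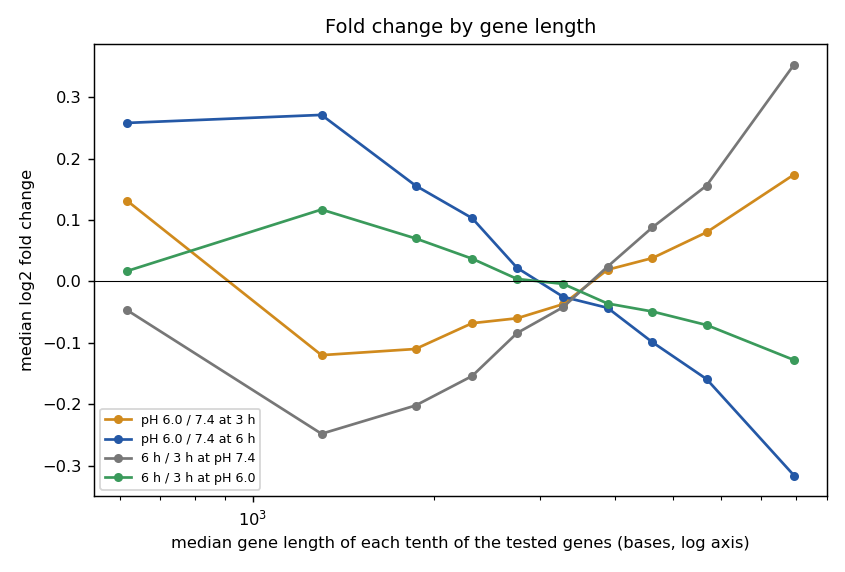
Median log2 fold change (y axis) of each decile of the 15630 tested genes, ordered by gene length (x axis, bases, log scale), for pH at 3 h and 6 h and for time at each pH. The longest decile lies at -0.32 for pH at 6 h and at 0.35 for time at pH 7.4.

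The acid-handling genes given here were chosen before the data were examined and are given whether or not they passed. As lists, acid and bicarbonate transporters (adjusted p = 0.274 at 3 h and 0.957 at 6 h), carbonic anhydrases (0.455 and 0.278) and proton-sensing receptors and channels (0.701 and 0.486) did not pass. The lactate and proton exporter SLC16A3 rose with acid at 3 h (0.67 ± 0.10, adjusted p = 8.57e-05) and at 6 h (1.48 ± 0.11, adjusted p = 2.54e-10), where pH 7.4 libraries held 21.2 ± 1.96 CPM and pH 6.0 libraries 59.2 ± 2.33 CPM (SD). The related transporter SLC16A1 fell at 6 h (-0.53 ± 0.08, adjusted p = 5.4e-06) and had 0.13 ± 0.07 at 3 h (adjusted p = 0.23). The exchanger gene SLC9A2 rose at 6 h (0.39 ± 0.10, adjusted p = 0.0025), with 0.16 ± 0.10 at 3 h (adjusted p = 0.265, and 0.00947 without the second library at pH 7.4). The apical exchanger SLC9A3 passed at 3 h (-0.64 ± 0.20, adjusted p = 0.0389) but not with the length and GC correction (-0.507, adjusted p = 0.0819). Nor did it pass without the first or the second library at pH 7.4 (0.178 and 0.132) or without the second or the third at pH 6.0 (0.147 and 0.128), where its log2 change was -0.594 to -0.483. At 6 h it had -0.01 ± 0.20. The chloride/bicarbonate exchanger SLC26A3 fell at 6 h (-0.77 ± 0.19, adjusted p = 0.00394), with -0.06 ± 0.19 at 3 h.

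The chloride channel CFTR rose at both times (0.51 ± 0.10 and 0.39 ± 0.10, adjusted p = 0.00132 and 0.00307), as did the carbonic anhydrase CA12 (0.37 ± 0.07 and 0.31 ± 0.07, adjusted p = 0.00133 and 0.0017). CA2 rose at 6 h (0.52 ± 0.13, adjusted p = 0.00197), and CA9 had -0.16 ± 0.12 and 0.00 ± 0.12 with adjusted p = 0.366 and 0.977. The bicarbonate cotransporter SLC4A7 rose at 3 h (0.59 ± 0.13, adjusted p = 0.00267). Its value at 6 h was 0.27 ± 0.13 (adjusted p = 0.0841), which passed with the stricter filter (0.049), with the length and GC correction (4.54e-04) and without the third library at pH 7.4 (0.0359) or at pH 6.0 (0.0468). SLC26A6 had -0.16 ± 0.10 and -0.21 ± 0.10 (adjusted p = 0.259 and 0.0842). The value at 6 h passed with total counts (0.0435) and without the third library at pH 6.0 (0.00788). The chemokine CXCL8 rose at 6 h (1.47 ± 0.25, adjusted p = 3.27e-04). At 3 h it had 0.70 ± 0.31 (adjusted p = 0.131), which passed with DESeq2 (0.0429) and without the first library at pH 7.4 (0.0305). SLC4A4, GPR4 and GPR132 held 66, 6 and 34 counts over all 12 libraries and GPR65 held 0, all under the filter. TXNIP was not analysed here. SLC16A1, SLC16A3, SLC9A3, CFTR and CA9 overlap other annotated exons, so their counts are uncertain to that extent.

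The averaged effect of pH, the mean of the effects at 3 h and 6 h, used 6 libraries against 6. It took in 6670 changed genes, 3149 higher and 3521 lower, and 485 of the higher and 306 of the lower genes moved at least 2-fold. The majority turned with the stricter filter (2967 higher and 2690 lower), without the first library at pH 6.0 and 3 h (3247 and 3230) and without any 1 of the pH 6.0 libraries at 6 h. The effects at 3 h and 6 h shared no library and had a Pearson r of 0.48 and a Spearman correlation of 0.34 across 15630 genes, which are not independent replicates. Genes higher at both times numbered 690, against 326 for independent lists. Genes lower at both times numbered 983 against 364, and genes changed in opposite directions 201 against 690. Of the 2937 genes changed at 3 h, 57.0% changed the same way at 6 h, which is 1673 genes (1109 without the third library at pH 6.0 and 3 h). With DESeq2's fold changes over 30685 genes, low counts included, r was 0.19.

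**Figure D4:**
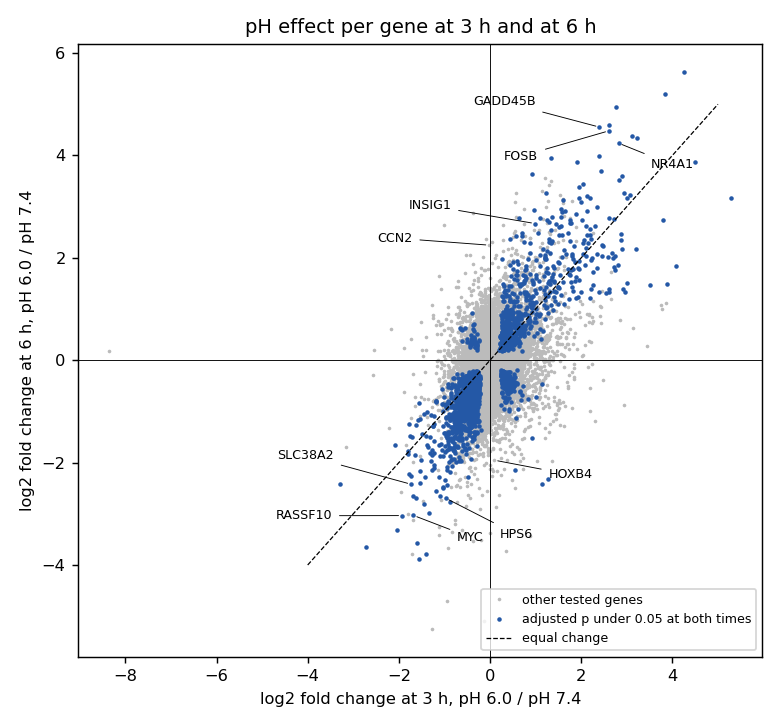
Log2 fold change of each tested gene for pH 6.0 against pH 7.4 at 3 h (x axis) and at 6 h (y axis). Blue points changed at both times, 690 upward and 983 downward, and 201 in opposite directions; the dashed line marks equal change.

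The interaction asked whether the effect of pH at 6 h differed from that at 3 h. The matricellular gene CCN2 held 38.7 ± 2.89 and 38.2 ± 4.72 CPM at pH 7.4 and 6.0 at 3 h, but 30.7 ± 0.223 and 145.7 ± 23.2 CPM at 6 h (SD, n = 3), a log2 difference of 2.26 ± 0.15 between the effects (adjusted p = 1.91e-09). GADD45B (2.16 ± 0.17), the immune surface marker CD83 (2.13 ± 0.26), the receptor tyrosine kinase KIT (2.05 ± 0.43) and RND1 (1.96 ± 0.36) followed. The largest negative differences were those of the non-coding AC012531.1 (-3.31 ± 0.50), Z83843.1 (-2.44 ± 0.20) and AL359955.1 (-2.28 ± 0.30), the homeobox gene HOXB4 (-2.04 ± 0.28) and the antisense transcript HOXB-AS3 (-1.83 ± 0.37). HOXB4 went from 13.2 ± 1.54 CPM at pH 7.4 to 3.43 ± 0.517 CPM at pH 6.0 at 6 h, against 8.36 ± 2.86 and 8.87 ± 0.937 CPM at 3 h (SD). In all, 4589 genes differed, 2048 with a positive and 2541 with a negative difference (2101 and 1622 after the length and GC correction). The estimates at both times had the same sign and were larger at 6 h for 1660 of these genes, and had the same sign and were smaller for 96. They had opposite signs for 2833, although of the 1874 genes changed at both times 201 moved in opposite directions.

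Cholesterol synthesis and heat shock genes were the lists that differed between the times with either correlation. The effect on cholesterol genes was larger at 6 h for 20 of 25 (21 adjusted over the list alone), with a median of 0.69 and at an adjusted p = 1.22e-23 for the list and an adjusted p = 0.044 with an estimated correlation. MSMO1 differed by 1.92 ± 0.12 and INSIG1 by 1.69 ± 0.12. The effect on heat shock genes was larger for 17 of 26 (20 adjusted over the list alone), with a median of 0.59 and at an adjusted p = 5.98e-12 for the list and an adjusted p = 0.044 with an estimated correlation. DNAJB1 differed by 1.57 ± 0.12. Ribosomal proteins had a positive difference in 61 of 73 cases (66 adjusted over the list alone), at an adjusted p = 1.39e-23 for the list and an adjusted p = 0.282 with an estimated correlation. RPL35A differed by 0.81 ± 0.14. Oxidative phosphorylation genes did in 36 of 54 (44 adjusted over the list alone), at an adjusted p = 3.86e-14 for the list and an adjusted p = 0.282 with an estimated correlation. NDUFB10 differed by 1.07 ± 0.19. Tight junction genes had a negative difference in 11 of 24 cases and a positive one in 3 (14 and 3 adjusted over the list alone), at an adjusted p = 0.00421 for the list and an adjusted p = 0.186 with an estimated correlation. CLDN1 differed by -1.19 ± 0.11. Among single genes the difference also passed for HERPUD1 (1.23 ± 0.10), NDRG1 (1.34 ± 0.14), PGAM1 (1.05 ± 0.11) and NFKBIA (1.13 ± 0.14) upward, and for MYC (-1.35 ± 0.14), AXIN2 (-1.56 ± 0.14), the prolyl hydroxylase EGLN3 (-1.16 ± 0.17) and the desmosome gene DSP (-0.94 ± 0.16) downward. Among acid-handling genes it was 0.81 ± 0.15 for SLC16A3 (adjusted p = 4.15e-04) and -0.67 ± 0.11 for SLC16A1 (adjusted p = 1.25e-04). CCN2, HOXB4, HOXB-AS3, DNAJB1, AXIN2, SLC16A1 and SLC16A3 overlap other annotated exons, and AL359955.1 and RPL35A have near copies, so these values are uncertain.

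Time in saline of pH 7.4 gave the background against which acid acted. The kinesin gene KIF21B went from 14.6 ± 2.07 CPM at 3 h to 58.1 ± 5.06 CPM at 6 h (SD, n = 3; log2 2.00 ± 0.12, adjusted p = 5.3e-10). ACSL6, an acyl-CoA synthetase (1.76 ± 0.17), the cystine transporter SLC7A11 (1.71 ± 0.11), glycerol kinase GK (1.60 ± 0.11) and the phosphatase PTPN13 (1.55 ± 0.11) rose as well. The glycolytic regulator PFKFB4 (-1.88 ± 0.23), the sulfate transporter SLC26A2 (-1.50 ± 0.17), the hypoxia-inducible MIR210HG (-1.47 ± 0.21), LCN12 (-1.35 ± 0.21) and adenylate kinase AK4 (-1.32 ± 0.16) fell most. In all, 4942 genes changed, 2695 higher and 2247 lower, 225 and 142 of them at least 2-fold. With total counts the split was 2093 higher and 3179 lower.

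Of the 44 lists, 22 changed with time at pH 7.4, 12 higher and 10 lower, and 2 also passed with an estimated correlation. ERK feedback genes rose in 18 of 23 cases (19 adjusted over the list alone), with a median of 0.75 and at an adjusted p = 2.37e-21 for the list and an adjusted p = 0.0244 with an estimated correlation. PHLDA1 rose by 1.11 ± 0.08 and SPRY4, an inhibitor of receptor signalling, by 0.97 ± 0.08. Tight junction genes rose in 12 of 24 cases (14 adjusted over the list alone, with 1 lower), at an adjusted p = 4.13e-07 for the list and an adjusted p = 0.0499 with an estimated correlation. CLDN1 rose by 1.28 ± 0.08 and TJP1 by 0.83 ± 0.09. These are long genes (median 4493.5 bases against 2994.5 over all tested genes), and long genes had higher medians with time, but tight junction genes still passed after the length and GC correction (adjusted p = 1.18e-07), with a median of 0.22 against 0.29. ATF4 targets rose in 24 of 35 cases (26 adjusted over the list alone), at an adjusted p = 7.15e-21 for the list and an adjusted p = 0.0512 with an estimated correlation. The cysteine-forming enzyme CTH rose by 1.25 ± 0.10 and SLC38A2 by 1.02 ± 0.08. Cholesterol synthesis genes fell in 21 of 25 cases and rose in 1, also 21 and 1 adjusted over the list alone, at an adjusted p = 2.62e-15 for the list and an adjusted p = 0.068 with an estimated correlation. MSMO1 (-1.03 ± 0.08), the epoxidase SQLE (-0.87 ± 0.08) and INSIG1 (-0.93 ± 0.09) fell. Glycolysis genes fell in 15 of 26 cases and rose in 3 (16 and 3 adjusted over the list alone), at an adjusted p = 5.78e-05 for the list and an adjusted p = 0.199 with an estimated correlation. PGAM1 (-0.90 ± 0.08) and LDHA (-0.58 ± 0.09) were among those that fell, and the HIF target NDRG1 fell by 1.23 ± 0.10 on the log2 scale.

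Ribosomal proteins fell in 57 of 73 cases (62 adjusted over the list alone), at an adjusted p = 6.21e-14 for the list and an adjusted p = 0.4 with an estimated correlation. RPL35A fell by 0.48 ± 0.10 on the log2 scale. Beside this the median log2 change over time at pH 7.4 was 0.35 in the longest decile of genes and -0.25 in the second decile, but -0.05 in the shortest. Desmosome and adherens junction genes rose in 13 of 18 cases (14 adjusted over the list alone), at an adjusted p = 3.78e-06 for the list and an adjusted p = 0.199 with an estimated correlation. DSP rose by 0.79 ± 0.11 and EVPL by 0.77 ± 0.09. The median of adherens junction and desmosome genes, which are long (5629.5 bases), was 0.32, near that of the longest decile, and 0.23 after the length and GC correction (adjusted p = 2.44e-05). FOXO targets rose in 12 of 23 cases and fell in 3 (14 and 3 adjusted over the list alone), at an adjusted p = 5.93e-04 for the list and an adjusted p = 0.0784 with an estimated correlation. The insulin receptor substrate IRS2 (1.05 ± 0.10) and the cell cycle inhibitor CDKN1A (0.80 ± 0.10) were among those that rose. The clock gene RORA (1.23 ± 0.11), the survival gene MCL1 (0.90 ± 0.07), the death receptor TNFRSF10B (0.78 ± 0.07), the autophagy kinase ULK1 (0.70 ± 0.08) and the YAP target LATS2 (0.78 ± 0.09) rose as well. ACSL6, SLC7A11, GK, PTPN13, PFKFB4, SLC26A2, PHLDA1, RORA, MCL1 and TNFRSF10B overlap other annotated exons and are uncertain to that extent.

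With time at pH 6.0, immediate early and heat shock genes rose as lists (adjusted p = 0.00332 and 0.00199 with an estimated correlation). The ERK phosphatase DUSP5 went from 35.7 ± 0.175 CPM at 3 h to 175.9 ± 18.4 CPM at 6 h (SD, n = 3; log2 2.30 ± 0.10, adjusted p = 2.8e-13). FOSB (2.20 ± 0.14), TENT5B (2.18 ± 0.19), CSRNP1 (2.18 ± 0.08) and CXCL8 (2.17 ± 0.27) rose similarly. HPS6 (-1.85 ± 0.12), AXIN2 (-1.61 ± 0.11), RASSF10 (-1.52 ± 0.15), HOXB3 (-1.50 ± 0.13) and CDX2, the intestinal homeobox factor (-1.44 ± 0.09), fell most. In all, 3050 genes changed, 1351 higher and 1699 lower, 220 and 279 of them at least 2-fold. The count fell to 1915 without the third library at pH 6.0 and 3 h. The split was 773 higher and 2499 lower with total counts, which moved the median of all genes to -0.10, and 2311 higher and 1525 lower after the length and GC correction.

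Of the 44 lists, 20 changed with time at pH 6.0, 19 higher and 1 lower, and 11 also passed with an estimated correlation. Immediate early genes rose in 31 of 37 cases and fell in 1 (31 and 2 adjusted over the list alone), at an adjusted p = 2.03e-60 for the list and an adjusted p = 0.00332 with an estimated correlation. MAFF rose by 1.78 ± 0.08 and NR4A1 by 1.75 ± 0.09. Heat shock genes rose in 20 of 26 cases and fell in 1 (21 and 1 adjusted over the list alone), at an adjusted p = 9.42e-30 for the list and an adjusted p = 0.00199 with an estimated correlation. DNAJB1 rose by 1.67 ± 0.09 and HSPA1B by 1.49 ± 0.10. ERK feedback genes rose in 15 of 23 cases and fell in 2, also 15 and 2 adjusted over the list alone, at an adjusted p = 3.7e-27 for the list and an adjusted p = 0.00372 with an estimated correlation. EPHA2 rose by 1.57 ± 0.08 and the growth factor HBEGF by 1.90 ± 0.11. ATF4 targets rose in 21 of 35 cases and fell in 2 (22 and 4 adjusted over the list alone), at an adjusted p = 2.07e-15 for the list and an adjusted p = 0.033 with an estimated correlation. The phosphatase subunit PPP1R15A (1.81 ± 0.08), ATF3 (1.55 ± 0.09) and DDIT3 (1.24 ± 0.12) rose. NF-kB targets rose in 17 of 32 cases and fell in 1, also 17 and 1 adjusted over the list alone, at an adjusted p = 2.5e-13 for the list and an adjusted p = 0.0207 with an estimated correlation. NFKBIE rose by 1.47 ± 0.12 and the chemokine CCL20 by 1.47 ± 0.12.

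The p53 targets rose in 11 of 25 cases and fell in 1 (13 and 3 adjusted over the list alone), at an adjusted p = 5.44e-09 for the list and an adjusted p = 0.00792 with an estimated correlation. BTG2 rose by 1.26 ± 0.11 and the pro-apoptotic BBC3 by 1.19 ± 0.11. Apoptosis regulators were mixed, with 10 of 27 higher and 4 lower (12 and 5 adjusted over the list alone), at an adjusted p = 1.09e-04 for the list and an adjusted p = 0.0104 with an estimated correlation. The anti-apoptotic MCL1 rose by 1.33 ± 0.07. YAP targets rose in 6 of 20 cases and fell in 2, also 6 and 2 adjusted over the list alone, at an adjusted p = 5.1e-06 for the list and an adjusted p = 0.0183 with an estimated correlation. CCN2 rose by 1.93 ± 0.11 and CCN1 by 1.43 ± 0.13. Genes of the unfolded protein response rose in 7 of 28 cases and fell in 1 (12 and 2 adjusted over the list alone), at an adjusted p = 3.37e-05 for the list and an adjusted p = 0.00792 with an estimated correlation. HERPUD1 rose by 1.24 ± 0.07 and XBP1 by 0.59 ± 0.08. Of 18 cAMP/CREB targets 11 rose and 1 fell (11 and 2 adjusted over the list alone), at an adjusted p = 7.99e-21 for the list and an adjusted p = 0.00199 with an estimated correlation. PER1 rose by 1.66 ± 0.09. Wnt targets were the list that fell, with 6 of 21 lower and 2 higher (7 and 3 adjusted over the list alone), at an adjusted p = 0.00193 for the list and an adjusted p = 0.0261 with an estimated correlation. MYC fell (-1.30 ± 0.10). FOXO targets tested as higher although their median was -0.02 (adjusted p = 0.0192, adjusted p = 0.143 with an estimated correlation). Of 23 members 5 rose and 4 fell (6 and 4 adjusted over the list alone). Some lists that rose here also rose with time at pH 7.4, with the preset but not with an estimated correlation. There 12 of 25 p53 targets rose and 3 fell (adjusted p = 0.012), and 11 of 20 YAP targets rose and 3 fell (5.93e-04). Apoptosis regulators had 11 of 27 higher and 3 lower (0.0108), and cAMP/CREB targets 9 of 18 and 1 (0.0108). Immediate early genes had 20 of 37 higher and 1 lower (4.13e-07).

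Across genes, the changes with time at both pH values had a Pearson r of 0.10 and a Spearman correlation of 0.03. Genes higher with time at both numbered 431 against 233 for independent lists, genes lower 258 against 244, and genes changed in opposite directions 512 against 487. NR4A1, AXIN2, HOXB3, DNAJB1, DDIT3, PER1, CCN2 and MCL1 overlap other annotated exons, and HSPA1B has a near copy, so these values are uncertain.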

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

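The tests of transcript length, GC content and scaling for a pattern in this part were chosen only after the pattern had been seen; the interaction test and the counts over other splits of the libraries were planned. Each result here was picked out because the effect of pH at 6 h differed from that at 3 h by the interaction test.

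The interaction took in 4589 genes. Among the 100 splits drawn of 200 possible within each time, 2 gave as many genes, the real one included; the other, with 6670 genes, exchanges the 6 h labels and so returns the averaged pH effect itself, and without it the highest other count was 4199. These splits ask whether pH had any effect, not whether its effects at 3 h and 6 h were equal. They therefore cannot exclude chance for the interaction count. For the averaged effect 1 of 100 splits, the real one with 6670 genes, was as large and the highest other gave 5068. Random splits within each time thus rarely gave that many genes, but they cannot show differences between cultures, which the labels do not record. The interaction also called 19 gene lists, but 8 of the 100 splits gave as many, up to 22, so chance cannot be excluded for that number of lists. For contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05: the real count was as large or larger in 1 of the 10 each time, at 2937 genes against at most 73 for pH at 3 h, and at 7342, 4942 and 3050 genes against at most 0 for pH at 6 h, time at pH 7.4 and time at pH 6.0. The same holds for lists, where the real 21, 22, 22 and 20 stand against at most 10, 16, 18 and 16 in these contrasts. The other splits called a median of 8, 13, 13 and 11 lists (10 for the interaction). They mix the groups unevenly and keep part of the real difference, so these medians do not show what chance alone gives. The number of lists called with the preset correlation is therefore not taken as evidence of an effect of pH or time. Of 91 genes named for pH at either time, 63 had an interaction past the threshold, against 29.4% of all tested genes. Apart from the fixed acid-handling genes, they were named for a large change or a small p at 3 h or 6 h in these same data. That choice favours a difference between the times, so their share does not describe genes in general.

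Among single genes, the log2 difference between the effects at 6 h and at 3 h was 2.26 for CCN2, 2.16 for GADD45B, 2.13 for CD83, 2.05 for KIT and 1.96 for RND1. It was -3.31 for AC012531.1, -2.44 for Z83843.1, -2.28 for AL359955.1, -2.04 for HOXB4 and -1.83 for HOXB-AS3. In stress and signalling genes it was 1.57 for DNAJB1, 1.23 for HERPUD1, 1.13 for NFKBIA, -1.35 for MYC and -1.56 for AXIN2. In metabolic genes it was 1.92 for MSMO1, 1.69 for INSIG1, 1.34 for NDRG1, 1.05 for PGAM1, 1.07 for NDUFB10 and -1.16 for EGLN3, and for the ribosomal protein gene RPL35A it was 0.81. Junction genes differed by -1.19 (CLDN1) and -0.94 (DSP), and acid transporters by 0.81 (SLC16A3) and -0.67 (SLC16A1).

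Among lists, the median difference was 0.69 for cholesterol synthesis genes and 0.59 for heat shock genes, both of which also passed with an estimated correlation. With the preset correlation alone it was 0.65 for immediate early genes, 0.55 for cAMP/CREB targets, 0.43 for glycolysis, 0.28 for HIF targets, 0.34 for fatty acid and triglyceride synthesis, 0.32 for the ER unfolded protein response, 0.20 for NF-kB targets, 0.41 for V-ATPase subunits, 0.36 for G2/M genes and 0.33 for G1/S genes. It was -0.25 for interferon-stimulated genes, -0.37 for tight junction genes, -0.28 for adherens junction and desmosome genes and -0.26 for Wnt targets. After the length and GC correction these medians were closer to 0, at -0.16 for interferon-stimulated genes, -0.17 for tight junction genes, -0.08 for adherens junction and desmosome genes and -0.10 for Wnt targets, so a trend with length may account for part of them. The median length was 4493.5 bases for tight junction genes, 5629.5 bases for adherens junction and desmosome genes and 4307 bases for Wnt targets, against 2994.5 bases over all tested genes. The medians for ribosomal proteins (0.72), oxidative phosphorylation (0.66) and proteasome subunits (0.52) belong to the pattern weighed next.

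At 6 h, the 157 ribosomal protein, oxidative phosphorylation and proteasome genes had a median log2 change of 0.49 at pH 6.0, with 120 higher and 0 lower, and their median length was 1769 bases against 2994.5 bases over all tested genes. A trend with transcript length and GC content could raise them. Their median lay above all of 10000 random lists matched on length, GC content and expression (percentile 100, random median 0.31, central range 0.23 to 0.36). It was 0.41 after the correction. A trend as far as the matching and the correction capture it may thus account for part of the rise and not for all of it. The matching used 5 classes each of length, GC content and expression, so differences within a class were not matched. The random lists were also not matched on how far genes vary together, so the percentile may overstate how unusual the median is. The choice of scaling does not account for the rise either, since the lower of the medians with other scalings was 0.45. A shared regulation of these genes by pH therefore stays open as a hypothesis, as does a technical factor that moves them together, such as RNA handling, which the labels do not record. The lists did not pass with an estimated correlation (adjusted p = 0.438, 0.438 and 0.484), and their genes also varied together between libraries of the same group. From 3 h to 6 h at pH 7.4 their medians were -0.42, -0.40 and -0.25, with 57 of 73, 29 of 54 and 13 of 30 genes lower. At pH 6.0 the medians with time were 0.30, 0.28 and 0.27. The difference at 6 h thus holds a fall at pH 7.4 as well as a rise at pH 6.0. None of these changes with time passed with an estimated correlation.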

How the results depend on the processing

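The length and GC correction was chosen after the results were seen; all other settings were planned. The test against a fold change of 1.2, which asks for larger changes by construction, left 700 genes changed by pH at 3 h, 4464 genes changed by pH at 6 h, 2592 genes changed by pH averaged over both times, 2357 genes whose pH effect differs between 6 h and 3 h, 1666 genes changed from 3 h to 6 h at pH 7.4 and 1058 genes changed from 3 h to 6 h at pH 6.0. With an estimated correlation, 1 of the gene lists called by pH at 3 h was left, 10 of the gene lists called by pH at 6 h, 2 of the gene lists whose pH effect differs between 6 h and 3 h, 2 of the gene lists called from 3 h to 6 h at pH 7.4 and 11 of the gene lists called from 3 h to 6 h at pH 6.0. Leaving out 1 library gave 1648 to 3617 genes changed by pH at 3 h (1661 without the first library at pH 7.4, 1649 without the second at pH 6.0) and 1915 to 3408 genes changed from 3 h to 6 h at pH 6.0; for the first count, the cause was not tested. The agreement of the pH effect at 3 h and 6 h (Pearson r) was 0.19 with DESeq2, over more genes with low counts, and 0.41 to 0.51 with 1 library left out. The other gene counts stayed within 1.5 times under DESeq2, other scalings, other filters and the correction, as did those for pH at each time and for time at each pH in a fit of only the groups compared. The list counts were recomputed with median-of-ratios factors, the stricter filter, the correction and 1 library left out, and stayed within 1.5 times.

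Of 233 log2 fold changes of named genes, 222 of them past the threshold, 2919 of 2952 alternatives kept direction and side of the threshold, 12 lost and 9 gained significance and 12 changed sign. Apart from the fixed acid-handling genes, these genes were chosen from the same fit for a large change or a small p. Their stability was therefore largely set by the choice and does not carry over to the other changed genes. The sign changes were all in values near 0 that did not pass: SLC26A3 for pH at 3 h (-0.2 to 0.176 with 1 library left out), SLC9A3 for pH at 6 h (0.034 with the stricter filter, -0.069 to 0.127 with 1 library left out) and CA9 for pH at 6 h (0.005 with DESeq2 and with median-of-ratios factors, 0.039 with the stricter filter, -0.083 to 0.092 with 1 library left out). The cause was not tested.

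Whether the replicate numbers pair the libraries stays open: of 18 pairs with the same number, 2 had deviations from the group means correlated above 0.1 (from -0.13 to 0.23), and 5 of 12 libraries correlated best with their own number. Every gene count was higher with the number as a block than in the main fit. With the replicate number as a block there were 3231 genes changed by pH at 3 h, 7457 genes changed by pH at 6 h, 6825 averaged over both times, 4774 for the interaction, 5115 and 3289 with time at pH 7.4 and pH 6.0, and 19, 22, 19, 22 and 21 lists for pH at 3 h, pH at 6 h, the interaction and time at each pH; r was 0.47.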

Other observations

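The family scan and the tests of length, GC content and scaling in this part were chosen only after the results were seen.

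Several lists, not described so far for pH at 6 h, did not pass as a whole there, and the counts of their changed members stand beside 47.0% of all tested genes changed. Of 24 genes of fatty acid oxidation and PPAR targets 9 rose and 3 fell (adjusted p = 0.0769), and of 37 lysosomal genes 15 rose and 6 fell (adjusted p = 0.389). NRF2 targets had 11 higher and 7 lower of 30 (adjusted p = 0.389), and autophagy genes 6 higher and 11 lower of 32 (adjusted p = 0.698). YAP targets had 5 higher and 11 lower of 20, with a median of -0.37 but a mean of 0.08 (adjusted p = 0.724). Mucin and goblet cell genes had 4 higher and 6 lower of 21 (adjusted p = 0.836), genes of enterocyte and colonocyte differentiation 3 higher and 5 lower of 23 (adjusted p = 0.957), and genes of adenosine signalling 4 higher and 3 lower of 15 (adjusted p = 0.776). Replication-dependent histone genes rose in 7 of 13 cases and fell in 0, also 7 and 0 adjusted over the list alone, with H2BC21 at 1.63 ± 0.18 (SE, n = 3), and passed as a list (adjusted p = 0.0266, adjusted p = 0.19 with an estimated correlation), but replication-dependent histones did not pass after the length and GC correction (adjusted p = 0.201). Histone genes are near copies of each other, so these counts are uncertain. Of 13 mitochondrially encoded genes 4 fell and 0 rose at 6 h (adjusted p = 0.351).

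In a scan of 89 gene families by the stem of their symbols, 12 changed as a whole for pH at 6 h with the preset correlation and none with an estimated one. Genes of mitochondrial ribosomal proteins (MRPL) rose in 23 of 47 cases and fell in 2 (adjusted p = 0.00596, adjusted p = 0.8 with an estimated correlation). ZBTB genes fell in 20 of 38 cases and rose in 2 (adjusted p = 0.00281, adjusted p = 0.513 with an estimated correlation), ubiquitin-specific protease (USP) genes fell in 27 of 44 and rose in 5 (adjusted p = 0.00903, adjusted p = 0.71 with an estimated correlation), and TRIM genes fell in 24 of 49 and rose in 5 (adjusted p = 0.0196, adjusted p = 0.513 with an estimated correlation). After the length and GC correction the adjusted p was 0.0212 for ZBTB, 0.223 for MRPL, 0.226 for USP and 0.0713 for TRIM genes.

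The widest of these patterns is in the zinc finger genes named ZNF, of which 213 of 441 fell and 23 rose at pH 6.0 at 6 h, with a median log2 change of -0.38. Their median lay below all of 10000 random lists matched on length, GC content and expression (percentile 0, random median -0.06, central range -0.12 to 0.00). It was -0.30 after the correction and -0.37 or lower with the other scalings. Neither the choice of scaling nor a trend as far as the matching and the correction capture it may thus account for the whole. These random lists used 5 classes of each property too and were not matched on how far genes vary together either. The percentile may therefore overstate how unusual the median is. The 406 protein-coding members did not pass with an estimated correlation (adjusted p = 0.513), and reads shared between these related genes were not tested. A fall of short-lived messages in acid saline is a hypothesis that would need mRNA decay rates, which were not analysed here.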
